A study of Mus musculus with 12 samples.

How the data were processed

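H3K27ac libraries of E15.5 mouse whole cortex were compared between 3 WT (Prdm16 flox/flox) and 3 cKO (Emx1-Ires-Cre; Prdm16 flox/flox) samples. Per the labels' protocols, native chromatin was digested with micrococcal nuclease and precipitated with antibody ab4729, and libraries were amplified for 11 PCR cycles and size-selected between 100 and 800 bp. Per the submitters' processing notes, FastQC, cutadapt, Bowtie2 2.2.8 and MACS2 2.1.1 were used with the mm10 build; their roles and parameters are not given in the sources used here. The deposited files are broad peak lists, 1 per H3K27ac library. It is not stated whether input libraries served as control, or what was combined before peaks were called. The 6 input libraries were not analysed here.

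Each deposited list gives positions, a display score (not used), a fold enrichment ratio per peak (not used for comparisons) and -log10 p and -log10 q values per peak, all made by the authors' peak caller. The lowest -log10 q in a list was 1.31 to 1.39. The -log10 values served only to rank or filter peaks within a list. Peak lists hold no read counts, so sequencing depth is unknown, and a longer list can come from a deeper library, a stronger precipitation or more acetylated chromatin. Lists held 48168 to 75563 peaks.

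Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Library batches were read from the library identifiers (batch A with 4 libraries, batch B with 2, both genotypes equally). Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 21883 protein-coding genes on the main chromosomes. That table gives neither strand nor exons. The planned share of peaks within 2 kb of a transcription start site was therefore replaced by the share within 2 kb of either end of a protein-coding gene, and positions are given as inside or outside a gene without exon or intron. Of 231 genes on the fixed lists, 230 were in the table and 187 were tested.

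Per-library measures were compared by two-sided exact permutation tests over all 20 assignments of the labels (smallest possible p 0.1), with Benjamini-Hochberg adjustment over 4 measures. Similarity was the Jaccard index of covered bases for 15 library pairs. Regions were formed by merging peaks of the 6 lists that overlapped by at least 1 bp or touched, and a library was present where a peak overlapped the region. Shares of regions carry exact (Clopper-Pearson) 95% intervals. Covered length per gene locus was the number of bases under peaks in the gene body plus 20 kb on each side. It was scaled to the same total in every library, log2 transformed after adding 500 bp, and tested with limma (lmFit and eBayes, trend and robust off) with batch as covariate. Genes needed a mean of at least 1000 bp, calls used a Benjamini-Hochberg adjusted p below 0.05, and every adjusted p for a gene is from limma. Covered length grows with the number and width of called peaks and not with their height, and neighbouring genes can share a window. Gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over 17 lists), again with an estimated correlation, and with fry.

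The tests, lists and alternatives were fixed before the data were examined. So was the rule for naming: Prdm16; the 15 genes per direction with the largest log2 change among those that passed with one sign in all 3 same-numbered pairs; up to 4 members per list with the smallest p; and the 10 regions per direction with the highest value of the lowest library -log10 q. Further genes named in the closing section were chosen after their values were seen. The migration list includes Pdzrn3, which was known from the study's own publication, so its place there is not independent evidence.

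Alternatives were peaks with -log10 q of at least 5; lists reduced to the 48168 strongest peaks by -log10 p; each library left out; no batch covariate; a replicate block; pseudocounts of 100 and 2000 bp; no length filter; no scaling; quantile normalization; 2 kb around the gene ends or the gene body plus 100 kb; windows of 1 and 5 kb; at least 50% of a region covered; and merging across gaps of up to 1 kb. The scripts were tested on simulated data. All 200 regions planted in the cKO lists were recovered. For the cKO minus WT comparison of covered length over 15355 genes, 45 of 67 genes changed by 0.5 on the log2 scale were recovered, as were all 67 changed by 1 and all 66 changed by 2, with 15 unchanged genes called alongside.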

Results

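Acetylation of histone H3 at lysine 27, a mark of active promoters and enhancers, was mapped by native chromatin immunoprecipitation and sequencing in the cerebral cortex of mouse embryos at E15.5, when cortical neurons are being born. The wild-type (WT) embryos carried a floxed allele of Prdm16, which encodes a zinc-finger chromatin regulator of neural progenitors, without Cre. The conditional knockout (cKO) embryos also carried Emx1-Ires-Cre, which is active in dorsal forebrain progenitors and their progeny, to recombine that allele. Each genotype had 3 H3K27ac libraries, and the 6 matching input libraries were not analysed here. The deposited data are 1 peak list per library, so the depth in reads is unknown and all values below are numbers, positions and lengths of peaks. Library identifiers placed replicates 1 and 2 of both genotypes in one batch (batch A) and replicate 3 of both in another (batch B). Nothing in the labels says whether replicates came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical.

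The first comparison asked whether loss of Prdm16 changed the overall extent of H3K27ac. The WT lists held 66493, 75563 and 48168 peaks and the cKO lists 59209, 58682 and 55015. The mean was 63408 ± 13956 (SD, n = 3) in WT and 57635 ± 2285 (SD, n = 3) in cKO, a difference of -5773 peaks that was smaller than the spread between WT libraries (two-sided exact permutation test, p = 0.5, Benjamini-Hochberg adjusted p = 0.7 over 4 measures, smallest possible p 0.1). Peaks covered 76.4 ± 20.01 Mb in WT and 69.1 ± 4.90 Mb in cKO (SD, n = 3, exact p = 0.5, adjusted p = 0.7). In batch A the cKO mean was lower, by -12083 peaks and -15.8 Mb. In batch B the single cKO library was higher than the single WT library, by 6847 peaks and 9.68 Mb, so neither difference held within batches. Median peak width was 865 ± 33.0 bp in WT and 877 ± 26.6 bp in cKO (SD, n = 3, exact p = 0.7, adjusted p = 0.7), with differences of 9.5 bp in batch A and 17 bp in batch B. Peaks within 2 kb of either end of a protein-coding gene made up 22.9 ± 3.70% of the WT lists and 24.1 ± 0.687% of the cKO lists (SD, n = 3, exact p = 0.6, adjusted p = 0.7), with a difference of 2.90 points in batch A and -2.20 points in batch B. Without WT replicate 2, the longest list, the differences turned to 305 peaks, 0.513 Mb and -0.237 points. The width difference turned to -4.33 bp without WT replicate 3, to -0.667 bp without cKO replicate 1, to -25.3 bp among peaks with a -log10 q of at least 5 and to -55.8 bp in lists of equal length.

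**Figure D1:**
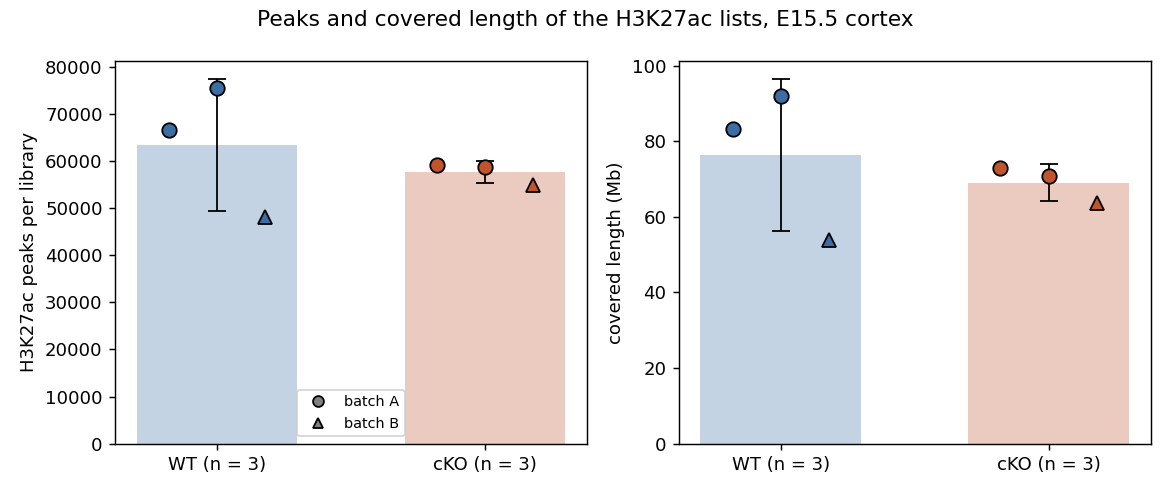
H3K27ac peaks per library (left axis, number) and covered length (right panel, Mb) for the 3 WT and 3 cKO libraries. Points are libraries (circles batch A, triangles batch B), bars are group means and error bars are SD; the WT libraries span 48168 to 75563 peaks and the cKO libraries lie between them, at 55015 to 59209.

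Pairs of libraries were then compared by the share of covered bases they had in common. This Jaccard index was 0.717 ± 0.002 among the 3 cKO pairs, 0.624 ± 0.071 among the 3 WT pairs and 0.660 ± 0.020 among the 9 pairs of different genotype (SD over pairs, which share libraries). The mean within genotypes exceeded the mean between genotypes by 0.011, and 3 of the 10 ways of splitting the 6 libraries into 3 and 3, the genotype split included, gave a difference as large. The 2 others put both batch B libraries on one side, and among the 6 splits with 1 batch B library on each side the highest other difference was 0.00398. Within batch A it was 0.0441, and batch B holds 1 library per genotype and gives no value. Without WT replicate 1, 2 or 3 it was 0.0227, 0.0231 or 0.0565, and without cKO replicate 1, 2 or 3 it turned to -0.00951, -0.0131 or -0.0138.

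The next comparison asked which sites carried H3K27ac in one genotype only. Merging the 6 lists gave 85918 regions, of which 39889 (46.4%) had a peak in all 6 libraries and 18188 in a single library. A peak in all 3 WT libraries and in none of the cKO libraries was found in 779 regions, and the converse in 298 regions. The strongest cKO-only region, ranked by the lowest of its 3 library -log10 q values (the authors' peak caller's own values), lay on chromosome 10 at 19835332 to 19837027 (mm10), outside any protein-coding gene and 10889 bp from Slc35d3, a nucleotide sugar transporter family gene. The next lay inside Pdzrn3, a gene of a PDZ-domain E3 ubiquitin ligase, on chromosome 6 at 101365564 to 101368466. Others lay inside Ncald (chromosome 15, 37498601 to 37501308), Tenm3 (chromosome 8, 49015282 to 49015533) and Sox6, which encodes a transcription factor of neural lineages (chromosome 7, 115663256 to 115664068). A pair of intergenic regions on chromosome 15, at 56615574 to 56617236 and 56846928 to 56847900, had the hyaluronan synthase gene Has2 as the nearest gene, 48390 and 152381 bp away. The remaining cKO-only regions among the 10 strongest were nearest to Ing2, Ap1s2 and Kif6.

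Among WT-only regions the strongest lay inside Thsd7b on chromosome 1 at 129897638 to 129898524, and others lay inside Fbxw4, Plpp1 and Umad1. The nearest gene to the region on chromosome 4 at 27945531 to 27945940 was Epha7, an ephrin receptor gene 867125 bp away, and the nearest to chromosome 1, 18758330 to 18758922, was the transcription factor gene Tfap2d, 344099 bp away. Further regions among the 10 strongest were nearest to Pik3c3, Slc25a3 and Rgs3.

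Reducing each list to its 48168 strongest peaks, the length of the shortest list, changed the balance between genotypes, giving 580 WT-only and 630 cKO-only regions, with 215 of the 779 and 101 of the 298 regions above overlapping them. On their larger side, other splits of the libraries gave up to 1485 regions with the lists as deposited and up to 262 with equal-length lists. Where each side held 1 batch B library, the larger side had up to 731 with the lists as deposited. The smaller sides of the other splits held 4 to 86 regions with the lists as deposited, against 298 for the genotype split. The WT-only count was 4494 without WT replicate 3, 1307 without cKO replicate 1 and 1177 without cKO replicate 2. The cKO-only count was 1016, 476, 484 and 649 without WT replicate 2 and cKO replicates 1, 2 and 3. Within batch A alone the counts were 5466 WT-only and 669 cKO-only regions. With a list left out, fewer lists must hold or lack a peak, so higher counts are built into these settings. Batch A alone relaxes the rule on both sides. With 3 against 3 libraries no single region can reach p < 0.05 in an exact test.

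**Figure D2:**
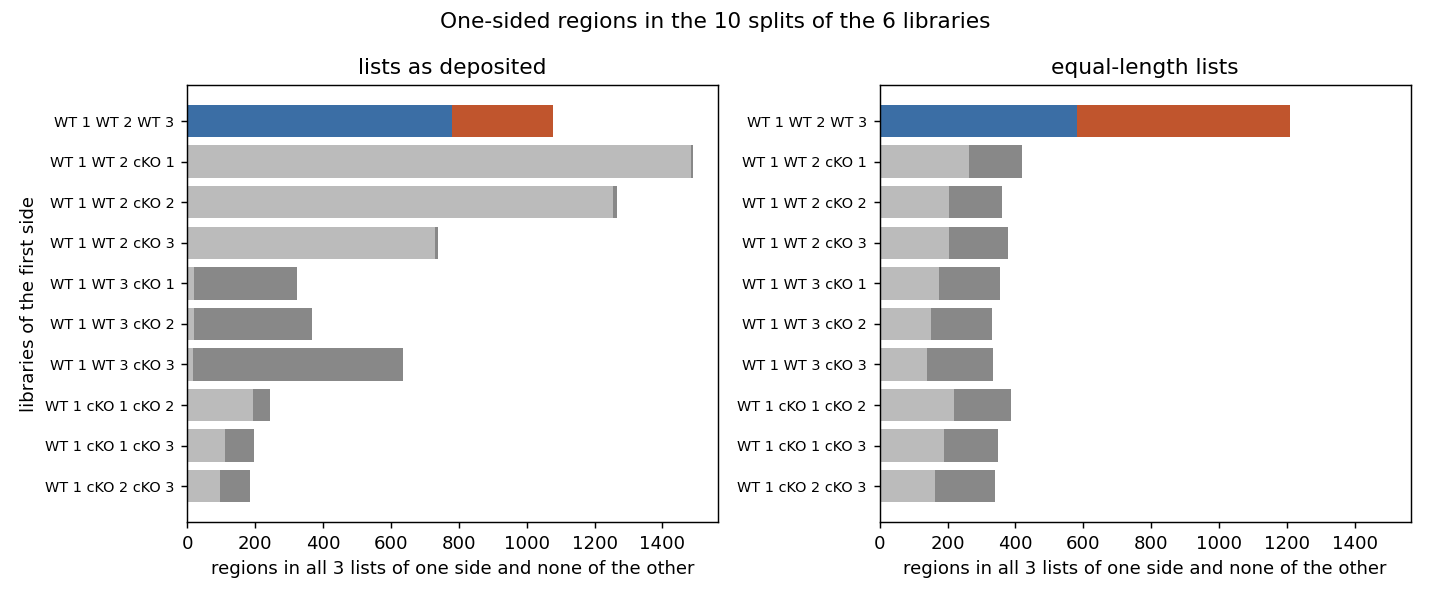
Number of merged regions with a peak in all 3 libraries of one side and none of the other (x axis), for the 10 splits of the 6 libraries (y axis, libraries of the first side), in the lists as deposited (left) and in lists of 48168 peaks each (right). The coloured bar is the genotype split (blue WT-only, orange cKO-only) and grey bars are the others, light grey for the first side; the genotype split totals 1077 regions on the left, where another reaches 1489, and 1210 on the right, where the highest other is 419.

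Regions of one genotype lay mostly away from gene ends. Only 33 of the 779 WT-only regions (4.24%, exact 95% interval 2.93 to 5.90) and 23 of the 298 cKO-only regions (7.72%, 4.96 to 11.4) were within 2 kb of either end of a protein-coding gene, against 31.6% of the regions found in all 6 libraries. Regions found in a single library had a share of 6.18%, and the larger sides of the other splits had 4.08 to 9.90%, so a low share was not particular to the genotype split. The intervals treat regions as independent and cover counting error only. About equal shares of the WT-only and cKO-only regions, 51.5% and 52.3%, overlapped a protein-coding gene body.

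H3K27ac was next summed over each protein-coding gene body plus 20 kb on each side as covered length. The Prdm16 locus itself (chromosome 4, 154316122 to 154637360) had a scaled covered length of 79817 ± 2400 bp in WT and 95254 ± 2396 bp in cKO (SD, n = 3), a log2 change of 0.25 ± 0.09 (SE) that did not pass (limma, adjusted p = 0.377). A covered length over the whole locus does not check the deletion. Of 15355 genes tested, 43 passed in 38 separate loci, 19 with longer and 24 with shorter covered length in cKO. All 43 had the same sign in all 3 same-numbered library pairs, and 0 lay on chromosome X or Y. They were called in these same libraries, so the shared sign is not separate evidence. At an unadjusted p under 0.05 there were 723 longer and 835 shorter. That is 1558 genes for the genotype split, while the other splits of the libraries had 420 to 1315. The split with 1315 held 1 batch B library on each side.

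Slc35d3 (chromosome 10, 19847917 to 19856634) stood apart: its window is listed at 0 bp in all 3 WT libraries and at 3607, 3101 and 3307 bp before scaling in the cKO libraries (limma adjusted p = 1.64e-06), and its neighbour Pex7, the gene of a peroxisomal import receptor, shares part of that window (log2 change 1.32). Mecom, a paralog of Prdm16 also known as Prdm3, rose from 3054 ± 1529 bp to 9355 ± 894 bp (SD, n = 3, log2 change 1.58 ± 0.23, SE, limma adjusted p = 0.0379). Pdzrn3 (chromosome 6, 101149607 to 101377897) rose from 17226 ± 1615 bp to 28745 ± 1909 bp (SD, n = 3, log2 change 0.72 ± 0.11, SE, limma adjusted p = 0.0385). Kremen1, a Dickkopf co-receptor in Wnt signalling, rose by 0.76 on the log2 scale, and Chd1, a chromatin remodeller, by 0.77. The pentraxin gene Ptx3 rose by 1.34 together with Veph1, whose gene body contains it (0.75), and Ppp1r14c, an inhibitory subunit of protein phosphatase 1, by 1.16. Rarres1 (0.85) and the carboxypeptidase inhibitor gene Lxn (0.79) share one locus. Gm2a (0.85), the coagulation factor gene F5 (0.84), Dnase2b (0.82) and the U6 snRNP gene Lsm6 (0.78) completed the 15 with the largest increases.

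Among the genes with shorter covered length in cKO, the window of the Wnt receptor gene Fzd5 (chromosome 1, 64730558 to 64737750) fell from 3532 ± 158 bp to 561 ± 416 bp (SD, n = 3, log2 change -2.00 ± 0.22, SE, limma adjusted p = 0.0119). Its neighbour Ccnyl1 (64691041 to 64725646) shares part of that window and changed by -1.02. Part of the lost length lies inside Ccnyl1, as with the WT replicate 1 peaks at 64711235 to 64713129 and 64719565 to 64720087. Near the high-coordinate end of Fzd5 each cKO list kept a peak, shorter than in WT. Minar1 fell from 2682 ± 136 bp to 346 ± 385 bp (SD, n = 3, log2 change -2.01 ± 0.21, SE, limma adjusted p = 0.0102). Sall4, a zinc-finger factor gene, changed by -1.18, the forkhead gene Foxb2 by -1.02 and the homeobox gene Barhl2 by -0.76. Foxb2 had 1432 ± 860 bp in WT and 443 ± 409 bp in cKO, and Esyt3 had 2013 ± 1381 bp and 748 ± 678 bp (SD, n = 3). The genotypes overlapped for these 2 of the 30 genes named: WT replicate 3 had 476 bp at Foxb2 and 438 bp at Esyt3, less than cKO replicates 1 and 2 (524 and 807 bp, and 1321 and 924 bp). Without the batch covariate neither passed (limma adjusted p = 0.527 and 0.760). Smoc1, which encodes a secreted matrix protein that antagonizes BMP signalling, changed by -0.99. Cacng5, a gene of a transmembrane AMPA receptor regulatory protein, changed by -1.46 and the protein phosphatase 1 regulator gene Ppp1r1c by -1.17. Tigit changed by -1.11, and its window overlaps Zbtb20, a transcription factor gene. Esyt3 (-0.99), Acss3 (-0.84), the centrosomal gene Cep19 (-0.81), Arfgef3 (-0.79) and Crocc2 (-0.74) completed the 15 largest decreases. These log2 changes are on the scale of covered length plus 500 bp, which understates the change of short covered lengths.

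The count of 43 depended on the libraries. It was 8, 3 and 2 without WT replicates 1, 2 and 3, and 66 and 2 without cKO replicates 2 and 3. Within batch A alone it was 2. Without replicate 3 of either genotype, the batch covariate absorbs the single batch B library that is left. Those 2 settings therefore nearly repeat the batch A comparison and are not separate checks. In every fit with a library left out, those of the 43 genes still tested kept their direction. Their median log2 change was 0.979 to 1.04 times that with all libraries, in largely the same libraries that gave the calls. Of the 30 genes named above, those still called were 7 of 28 tested, 3 of 28 and 1 of 29 without WT replicates 1, 2 and 3. Without cKO replicates 1, 2 and 3 they were 23 of 29, 27 of 29 and 1 of 30. Among peaks with a -log10 q of at least 5 they were 3 of 19, and in equal-length lists 13 of 24. Of all 30, 12 kept the call without the batch covariate, 19 with quantile normalization and 11 with the gene body plus 100 kb. Pseudocounts of 100 and 2000 bp kept 11 and 29, a replicate block 30, no filter 2 and no scaling 1. Equal-length lists gave 45 genes, 30 longer and 15 shorter, of which 14 were among the 43. Without scaling 1 gene passed, with longer covered length. With 2 kb around the gene ends 0 passed by limma (735 of 11020 tested at an unadjusted p under 0.05). Slc35d3 passed in every alternative in which it was tested (limma adjusted p 1.86e-07 to 0.0171). Pdzrn3 passed in equal-length lists and without cKO replicate 2 (limma adjusted p = 0.0252 and 0.0262), but not without WT replicates 1, 2 and 3 (0.0947, 0.132 and 0.156) or cKO replicates 1 and 3 (0.0873 and 0.147). Its call was also lost among peaks with a -log10 q of at least 5 (0.211), without the batch covariate (0.0546), with a pseudocount of 100 bp (0.0835), without the filter (0.105), without scaling (0.701), with 2 kb around the gene ends (0.462) and with the gene body plus 100 kb (0.0558), with a range of 0.00776 to 0.701 over its alternatives. Without WT replicates 1, 2 and 3 and cKO replicate 3 the limma adjusted p was 0.0956, 0.0955, 0.109 and 0.103 for Mecom and 0.0530, 0.0955, 0.14 and 0.133 for Fzd5. Mecom also lost its call in equal-length lists (0.0528), without the batch covariate (0.0801), with quantile normalization (0.0571), with a pseudocount of 100 bp (0.0879), without the filter (0.123), without scaling (0.701) and with 2 kb around the gene ends (0.694), with a range of 0.0041 to 0.701 over its alternatives. Its log2 change was 3.27 among peaks with a -log10 q of at least 5 and 0.78 with the gene body plus 100 kb. Fzd5 passed in equal-length lists (0.0153) and not with a pseudocount of 100 bp (0.0783), without the filter (0.0756) or without scaling (0.305), with a range of 7.48e-06 to 0.305.

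**Figure D3:**
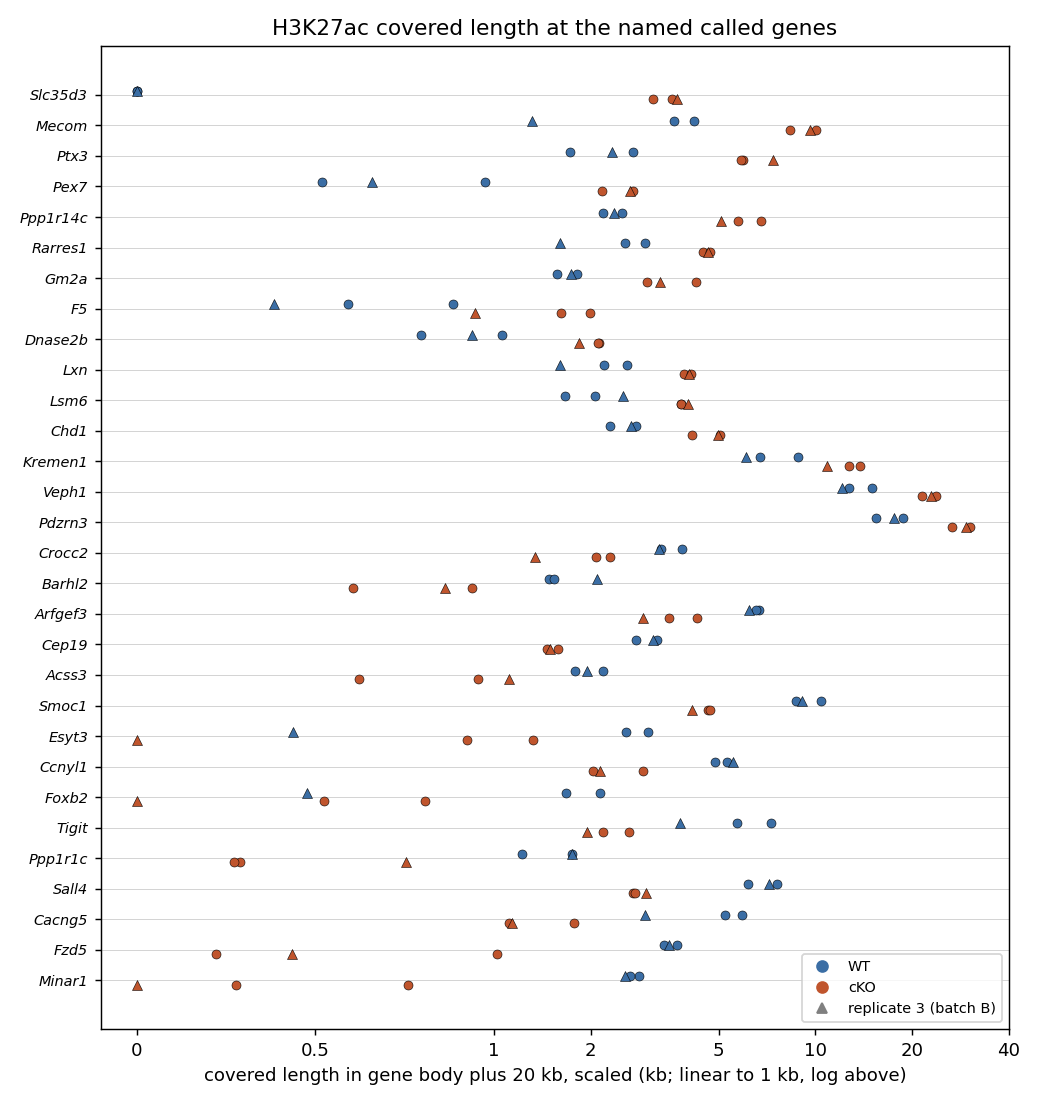
Scaled covered length (x axis, kb, linear to 1 kb and logarithmic above) of H3K27ac peaks in the gene body plus 20 kb for the 15 genes with the largest increase and the 15 with the largest decrease among those that passed. Each point is a library, blue WT and orange cKO, with triangles for replicate 3; Slc35d3 is at 0 in all 3 WT libraries and Pdzrn3 has means of 17226 bp in WT and 28745 bp in cKO.

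**Figure D4:**
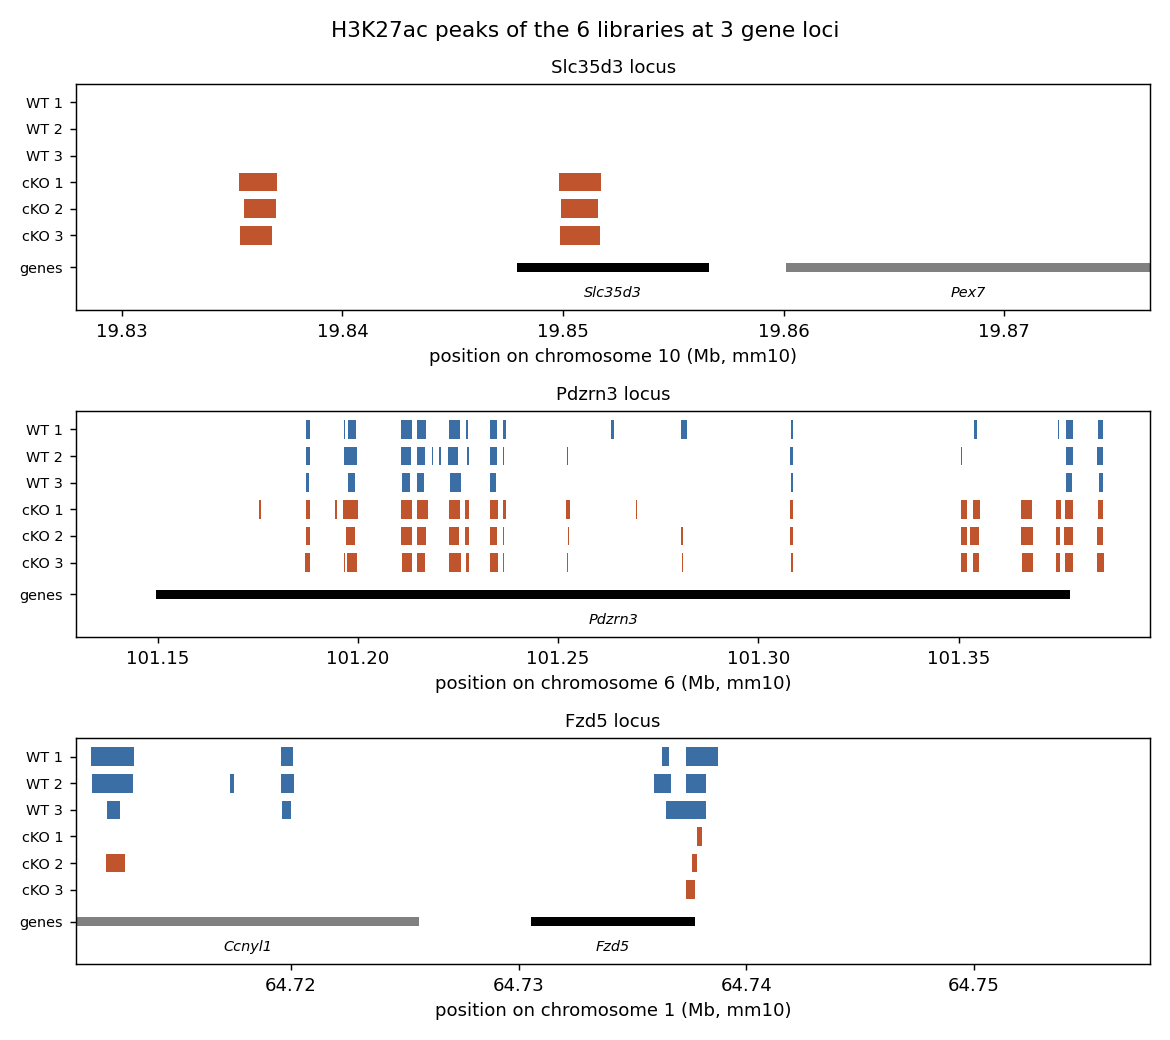
Peaks of the 6 libraries (rows, blue WT, orange cKO) along the Slc35d3, Pdzrn3 and Fzd5 loci (x axis, chromosome position in Mb, mm10), with protein-coding genes below (black, the named gene; grey, neighbours). The Slc35d3 window holds 2 peaks in each cKO library and none in WT, and the cKO-only region of Pdzrn3 lies at 101365564 to 101368466.

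Gene groups chosen for the embryonic cortex were then described. Of 14 upper-layer neuron genes measured, none passed singly, while the list was lower in cKO as a group (limma camera with a preset correlation of 0.01, adjusted p = 0.0195; adjusted p = 0.781 with an estimated correlation). Its median log2 change was -0.22, with 9 members negative and 5 positive. The lowest p values belonged to Unc5d, a netrin receptor gene (-0.65 ± 0.16, SE), the homeobox gene Cux1 (-0.33), Pou3f1 (-0.40) and the plexin gene Plxna4 (-0.30), and 1 gene, Unc5d, passed when adjusted over the list alone. Of 8 Cajal-Retzius and cortical hem genes measured, none passed singly or adjusted over the list alone, while the list was lower as a group (adjusted p = 0.0482; adjusted p = 0.781 with an estimated correlation), with Calb2 at -0.52, Wnt2b at -0.47, Trp73 at -0.32 and Ebf3 at -0.29. Both group calls were lost in equal-length lists (adjusted p = 0.205 and 0.944). Other splits of the 6 libraries also passed lists by camera. With both batch B libraries on one side, the smallest adjusted p went down to 0.000661. A split with 1 batch B library on each side passed 2 lists, with a smallest adjusted p of 0.0337. The group p-values alone therefore do not set the genotype split apart. The upper-layer list did not pass without WT replicate 1 (camera adjusted p = 0.111) or cKO replicate 2 (0.341), with a range of 0.00380 to 0.781 over its alternatives. It also failed among peaks with a -log10 q of at least 5 (0.0865), with quantile normalization (0.0620), with 2 kb around the gene ends (0.684) and with the gene body plus 100 kb (0.0620). Apart from these losses it passed in its alternatives. The Cajal-Retzius list did not pass without WT replicate 1 (0.0540), WT replicate 2 (0.641) or cKO replicate 2 (0.482). Its adjusted p ranged from 0.0199 to 0.944. Its call was also lost with -log10 q of at least 5 (0.777), without the batch covariate (0.103), filter (0.165) or scaling (0.202). Quantile normalization (0.0620), the gene body plus 100 kb (0.691) and pseudocounts of 100 and 2000 bp (0.05001 and 0.0737) lost it too. With autosomes only (0.0507) or 2 kb around the gene ends (0.684) it also failed. It passed only without cKO replicate 1, with a replicate block, in batch A alone or with either batch B library left out.

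Among 22 neuronal migration genes, 1 passed with longer covered length (Pdzrn3) and 21 did not (group adjusted p = 0.298); adjusted over the list alone, Pdzrn3 and the Slit receptor gene Robo2 (-0.62 ± 0.12, SE, limma adjusted p = 0.0909 over all genes) passed. Among 13 chromatin partner and PRDM family genes, Mecom passed, also adjusted over the list alone, and 12 did not (group adjusted p = 0.626). None of the 20 radial glia genes passed over all genes or adjusted over the list alone (group adjusted p = 0.408), with Hes5 at 0.31, Ednrb at 0.31, Hes1 at 0.17 and Mfge8 at -0.16. None of the 13 intermediate progenitor genes passed over all genes and 1, the proneural factor gene Neurod4 (-0.72), passed adjusted over the list alone (group adjusted p = 0.298). None of the 13 deep-layer neuron genes passed over all genes, and 1, the forkhead factor gene Foxp2 (-0.45 ± 0.10, SE, limma adjusted p = 0.109), passed adjusted over the list alone (group adjusted p = 0.485).

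None of the 14 Notch genes (group adjusted p = 0.408) and none of the 16 BMP and TGF-beta genes (group adjusted p = 0.776) passed over all genes or adjusted over the list alone, with Hey2 at 0.37, Maml1 at 0.32, Notch2 at -0.23, Smad3 at 0.36 and Smad1 at -0.25. None of the 14 interneuron and ventral forebrain genes passed either way (group adjusted p = 0.260), with Maf at 0.47 and Npy at -0.45. Of 3 oligodendrocyte lineage genes, none passed over all genes and all 3 passed adjusted over the list alone, Sox10 (0.36) and Cspg4 (0.46) longer and Pdgfra (-0.29) shorter (group adjusted p = 0.485). The genotypes overlapped at all 3. At Sox10 and Cspg4, WT replicate 2 (2131 and 3095 bp) was above cKO replicate 2 (2123 and 3030 bp), and WT replicate 3 was lowest (958 and 1040 bp). At Pdgfra, WT replicate 3 (1943 bp) was below cKO replicate 1 (2450 bp). None of the markers of other cells passed over all genes or adjusted over the list alone: 6 vascular genes (group adjusted p = 0.641, tested lower with a mean of -0.02 and a median of 0.05), 6 microglia and macrophage genes (0.230) and 3 meningeal fibroblast genes (0.641). The same held for 7 genes of the brown fat and mitochondrial programme (0.298), 14 housekeeping genes (0.469) and 6 control genes that cortex should not express (0.776). With an estimated correlation the adjusted p was 0.781 for each of the 17 lists, and the smallest directional adjusted p by fry was 0.351. Tested by fry for changes in either direction, 6 lists passed, with the smallest adjusted p of 0.00466 for the Notch and the BMP and TGF-beta genes. That fry test asks whether members of a list change, not whether they change more than other genes. It was not run on the other splits of the libraries.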

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

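The tests of the peaks at Y-linked genes were chosen after the results were seen. The difference in list length between genotypes went in opposite directions in the library batches. The cKO minus WT difference was -12083 peaks and -15.8 Mb of covered length in batch A, where both cKO libraries were below both WT libraries, and 6847 peaks and 9.68 Mb in batch B, with 1 library per genotype. The difference between batches was not tested.

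Peaks on chromosome Y entered no comparison by themselves, and numbers above the 3 that a count of 0 allows drew attention. From 90 Mb on there were 9 in WT replicate 2, 7 in cKO replicate 2 and 7 in cKO replicate 3.

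Below 10 Mb on chromosome Y, cKO replicate 3 had 6 peaks and the other libraries 0. The 6 included peaks within 2 kb of Kdm5d, Eif2s3y, Uty and Ddx3y, which are Y-linked genes expressed widely in males. The length of the peak lists is argued against, since the highest number of such peaks in the 4 libraries with longer lists was 0. The sex of the embryos, male in that library alone, is a candidate explanation: all 5 libraries without these peaks had a peak at the high-coordinate end of Xist, the gene of the X-inactivation RNA, and cKO replicate 3 had none. The labels give no sex, and its effect on the genotype comparison stays open, as untested; 0 of the 43 called genes lay on a sex chromosome.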

How the results depend on the processing

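The alternatives with batch A alone (without both batch B libraries) and with autosomes only were chosen after seeing the data. The cause of a change was not tested, except that leaving out libraries leaves fewer samples and that dropping the length filter raised the genes tested to 17403. The exact permutation tests of the per-library measures are too small to pass the threshold in any setting, so they say nothing about stability. Equal-length lists give no difference in peaks per library, since all hold 48168. For the single genes and lists named, 1694 values kept their side of the threshold, 328 kept direction but lost the call, 6 gained one and 2 reversed. A reversal was counted only for genes called in either setting and for lists that passed in the main setting. Values without a call could therefore change direction among the 1694. A value with no call in either setting also counted as kept, so the 1694 do not measure how stable the calls were. The calls kept by the 30 named genes are given by setting in the Results, and in many settings most were lost. Of the summary results, 82 values kept their direction, stayed within 1.5 times of a count or stayed within the interval of a share. Beyond that, 28 counts were smaller and 12 larger, 10 differences reversed and 5 shares moved. Read depth is unknown, so its effect could not be examined.

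Over the libraries left out singly, the cKO minus WT difference ranged from -13393 to 305 peaks, from -18.6 to 0.513 Mb, from -4.33 to 28.7 bp of median width and from -0.237 to 3.29 points of the share at gene ends. The similarity difference ranged from -0.0138 to 0.0565. WT-only regions ranged from 876 to 4494, cKO-only regions from 310 to 1016, genes called from 2 to 66 and lists passing from 0 to 3. Higher region counts are built into these settings, since fewer lists must hold or lack a peak.

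The width difference was -25.3 bp among peaks with -log10 q of at least 5 and -55.8 bp in equal-length lists. WT-only regions numbered 390 with -log10 q of at least 5 and 5466 in batch A alone. cKO-only regions numbered 630 in equal-length lists and 669 in batch A alone. In batch A alone the rule is looser, since it holds fewer lists per genotype. The share of WT-only regions at gene ends was 6.15% with -log10 q of at least 5, 5.96% in batch A alone, 2.57% within 1 kb and 10.01% within 5 kb, and that of cKO-only regions 13.4% within 5 kb.

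Genes called by limma and lists passing were 21 and 0 with -log10 q of at least 5 and 45 and 0 in equal-length lists. They were 13 and 1 without the batch covariate, 12 and 1 with a pseudocount of 100 bp and 109 and 1 with 2000 bp. Without the filter they were 6 and 1, without scaling 1 and 1 and with quantile normalization 23 and 0. With 2 kb around the gene ends they were 0 and 0, with 735 of 11020 genes at an unadjusted p under 0.05. The gene body plus 100 kb gave 40 and 0, and 42 of the 43 genes had the same direction there. Batch A alone gave 2 and 3, and autosomes only 44 and 1. A block by replicate number gave 64 genes, 42 of them among the 43, and 2 lists. The labels do not say whether the numbers pair the libraries. With genotype means removed, covered lengths of same-numbered WT and cKO libraries correlated at 0.131, 0.064 and 0.262. Those of differently numbered ones correlated at -0.227 to 0.168. With an estimated correlation 0 lists passed. With 2 kb around the gene ends the Cajal-Retzius list turned its direction (adjusted p = 0.684), as did Ccnyl1 (log2 change 0.024).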

Other observations

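The splits of equal-length lists, the splits sorted by batch and the tests of list length and batch were chosen after the results were seen, as were the genes named in this paragraph. In equal-length lists several gene loci held more than one region specific to a genotype. The loci of Pdzrn3 and of the ion channel gene Trpm3 each held 4 cKO-only regions, and those of Sox6, Sox5 and Kremen1 each held 3. With the lists as deposited, Pdzrn3 held 1 and Sox5 and Kremen1 held 0. At Sox5 and Kremen1 a WT list therefore had a peak in the merged region before the lists were cut. The lowest -log10 q kept was 2.82, 3.32 and 1.32 in WT replicates 1 to 3 and 2.64, 2.41 and 2.32 in cKO replicates 1 to 3. Sox5 and Sox6 encode related transcription factors, and their total covered length did not pass (log2 change -0.03, adjusted p = 0.957, and 0.07, adjusted p = 0.879, by limma). The locus of the diacylglycerol kinase gene Dgki held 3 WT-only regions (log2 change -0.20, limma adjusted p = 0.541) and those of Fzd5 and the homeobox gene Meis2 each held 2. With the lists as deposited, Fzd5 held 1 WT-only region. Sox10 passed in equal-length lists (log2 change 0.81, limma adjusted p = 0.0284) and not with the lists as deposited. The homeobox genes Meis1 (-0.68) and Mkx (-0.67) and the ephrin receptor gene Epha6 (-0.63) were among the other genes with shorter covered length in cKO that passed.

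With the lists as deposited, each genotype count was set against the larger side of every other split. By that measure 3 of the 10 splits of the 6 libraries, the genotype split included, gave as many regions as the 779 WT-only regions. For the 298 cKO-only regions 7 did, with a highest other of 1485 for both. The difference of 0.011 between the similarity within and between genotypes was reached by 3 splits (highest other 0.0358). The splits above the genotype for WT-only regions, for the total of 1077 and for similarity were 2, both with the batch B libraries on one side. With 1 on each side the highest others were 731, 740 and 0.00398. For cKO-only regions the larger sides of 3 of the 5 others were still as large. The 298 are the smaller side of the genotype split, and the smaller sides of the other splits held 4 to 86 regions. The comparison by larger sides therefore cannot tell whether the cKO-only count is ordinary. Library batch and the length of the peak lists are both candidate explanations for the splits above the genotype, since with 48168 peaks in every list the highest total of another split was 419 against 1210 for the genotype. The batch B libraries have the shortest lists, 48168 and 55015 peaks, so batch and list length go together here. That the genotype split's own regions may come from genotype is a hypothesis, since 10 splits are too few for a share under 0.05, and in equal-length lists 1 of the 10, the genotype split itself, reached 1210.

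For the 43 genes with changed covered length, the median log2 change in equal-length lists was 1.01 times that in the deposited lists. The lower quartile was 0.885, over the 37 genes still tested. For those 37 this argues against the number of peaks per list as the whole cause. It does not exclude other differences in list length, since the equal-length lists still covered 53.9 Mb (WT replicate 3) to 76.2 Mb (WT replicate 2). The 43 genes were also chosen in the same peaks. The calls themselves shifted, with 14 of the 43 among the 45 called there. The genotype split gave the most calls, 1 of 10 splits reaching 43 (highest other 3) and 1 of 10 reaching 45 in equal-length lists (highest other 2). At an unadjusted limma p under 0.05 the splits lay closer, with 1558 genes for the genotype split and up to 1315 for another. In equal-length lists these numbers were 1667 and up to 817. With 10 splits there are too few for a share under 0.05. Of the gene lists, the genotype split passed 2 and the highest other split passed 5.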
